A study of Drosophila melanogaster with 3 samples.

How the data were processed

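DNA replication timing was measured in Kc167, a female Drosophila melanogaster cell line derived from embryos (genotype se/e), with 3 two-colour Agilent tiling arrays. Per the labels' protocols, cells grown at 25 °C were labelled with BrdU, a thymidine analogue that marks newly made DNA, under hydroxyurea, which stalls S phase by depleting nucleotides. One population marked early-replicating DNA: 1 mM hydroxyurea for 3 h, then 50 µg/ml BrdU for 21 h in the drug and a further 1 h after the wash. The other marked late-replicating DNA: hydroxyurea for 24 h, release for 3 to 4 h, then BrdU for 2 h. DNA carrying BrdU was recovered with an antibody, and both populations were labelled with different dyes and hybridised together on each array. The labels give channel 1 the dye Cy5 and channel 2 the dye Cy3 on arrays 1 and 2, and the opposite on array 3. They do not state which channel held the early population, so every direction is given here as higher in channel 1 or higher in channel 2.

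Each array has 243273 spots, of which 241469 are genomic probes, 529 positive controls and 1275 negative controls. Probes were 45 to 60 nt long, and those on the 6 main arms (2L, 2R, 3L, 3R, 4 and X) lay a median of 470 bp apart, with coordinates of FlyBase release 5.1 as the files give them. Per the file headers, the deposited intensity values were made by Agilent Feature Extraction 9.5.1.1, which subtracted background, removed spatial and multiplicative trends and applied 1 linear dye factor per channel. The deposited log10 ratio of red over green in the same files served only to check the direction of each array. The flags for outlier, saturated and well-above-background spots are also, per the file headers, those of the scanner software. The authors' deposited table holds, for each array, a log2 ratio and a mean log2 intensity. The submitters' processing notes name limma, with no version, and the authors' normalization is not given in the sources used here. Set against the scanner values, its ratios were red over green with array 3 not turned. After turning, their medians were 0.01, 0.01 and 0.00 on arrays 1, 2 and 3, their correlations with the scanner ratios across probes were 0.985, 0.988 and 0.966, and their slopes were 0.817, 0.830 and 0.762. Direction and centring were thus settled by comparison, while the reason for the smaller scale stays unknown.

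The value analysed was log2(channel 1 / channel 2) of the processed signals, with array 3 turned by its dye labels, control spots left out, and outlier-marked spots set to missing (781 arm probes on at least 1 array). Each array was centred on its median over probes of the 6 arms, with no loess or quantile step, since many regions may truly shift in an array of this kind. The centring makes the numbers of higher and lower windows nearly equal by construction, and higher in a channel means relative to this median. Ratios were averaged in 10-kb windows with at least 3 probes. Windows and single probes were tested with limma 3.58.1 (R 4.3.3; an intercept with empirical Bayes, two-sided), at a Benjamini-Hochberg adjusted p under 0.05. Domains were runs of adjacent windows called in one direction, broken by no more than 2 windows without a call or without enough probes. Arm means and the difference between the 2 Mb nearest the centromere and the rest of each arm are given as mean ± SD over the 3 arrays. A two-sided exact sign-flip test on 3 arrays cannot give a p below 0.25. Total signal was the mean log2 processed signal of both channels, corrected by a quadratic regression on probe GC and length. Stretches near the level of negative controls held at least 20 dim probes, no more than 10 kb apart, each under the 99th percentile of the 1275 negative control spots, and counted as near a chromosome end within 200 kb of the outermost probe. Other computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

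The window test was tested on simulated data: with 200 of 11788 windows changed, it recovered 4% of the 50 windows changed by 0.1 on the log2 scale, 66% of 50 changed by 0.25, 96% of 50 changed by 0.5 and all 50 changed by 1, with 1 false call. The adjusted threshold was stricter there than in the measured arrays, where most windows were called. Before the data were examined, the longest domain in each direction on each arm was fixed as the set of regions to name. Tests by gene, the gene lists, gene density and feature classes were also planned but not run, because the gene table used here belongs to assembly release 6 and coordinates were not converted between releases. Alternatives for signals, normalization, centring, probe filters, dye terms, window sizes and left-out replicates were computed. Arrays 2 and 3 were scanned on the same day. A random block for scan day could not be estimated with 3 arrays, and the ratios of that pair differed with an SD over windows of 0.08, against 0.05 for arrays 1 and 2 and 0.07 for arrays 1 and 3. Arrays 2 and 3, like arrays 1 and 3, had opposite dye orientations, whereas arrays 1 and 2 had the same. Between the pairs with opposite dyes, the pair scanned on the same day differed more, not less. With only 1 pair from the same day, an effect of scan day is not excluded. The labels number 3 separate extractions but do not say that they came from separate cultures. The p-values thus measure only the spread between these arrays, which may be technical and which limma shares in part across windows.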

Results

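Replication timing was profiled across the Drosophila Kc167 genome on 3 arrays of 1 group, each comparing BrdU-marked DNA of an early-labelled and a late-labelled population. Median processed signals lay between 1171 and 1224 in all 6 channels, against medians of 13.0 to 32.1 for negative control spots. In each channel 99.8% of the 241469 probes were well above background, and 6 arm probes were saturated on any array. The number of arrays, 3, limited the precision. After array 3 was turned by its dye labels, ratios of arrays 1 and 2 correlated across probes with a Pearson r of 0.983 (Spearman 0.985), arrays 1 and 3 with 0.971 (0.973) and arrays 2 and 3 with 0.969 (0.972). Probes are not independent replicates. Over 10-kb windows the 3 pairs gave r of 0.998, 0.997 and 0.997. Without turning, array 3 correlated at -0.97 with both other arrays.

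The first comparison asked which parts of the genome lay above or below the array median in the ratio between the populations. Kc167 chromosomes alternated between stretches higher in channel 1 and stretches higher in channel 2 along all 5 major arms, whereas chromosome 4 lay wholly on the channel 1 side. The 5th and 95th percentiles of the window means were -1.38 and 1.25 on the log2 scale, or 2.60-fold higher in channel 2 and 2.38-fold higher in channel 1. Of 11788 windows, 1198 (10.2%) had a mean above 1 and 1483 (12.6%) a mean below -1. The sign was the same on all 3 arrays in 11491 windows. By limma, 11228 windows (95.2%) passed an adjusted p of 0.05, with 5646 higher in channel 1 and 5582 higher in channel 2. The near-equal split follows from median centring, and a call means only that the ratio of a window differed from the array median. Centred on the mean, 5864 windows were called higher in channel 1 and 5405 higher in channel 2. With normexp on the mean and background signals, the counts of called windows fell to 4788 and 4589. The median SD over arrays was 0.04 per window, and the largest mean among windows that missed the threshold was 0.094 in size. At the level of single probes, 102941 were called higher in channel 1 and 103028 higher in channel 2, out of 236740. With normexp on the mean and background signals these counts fell to 67871 and 70900.

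**Figure D1:**
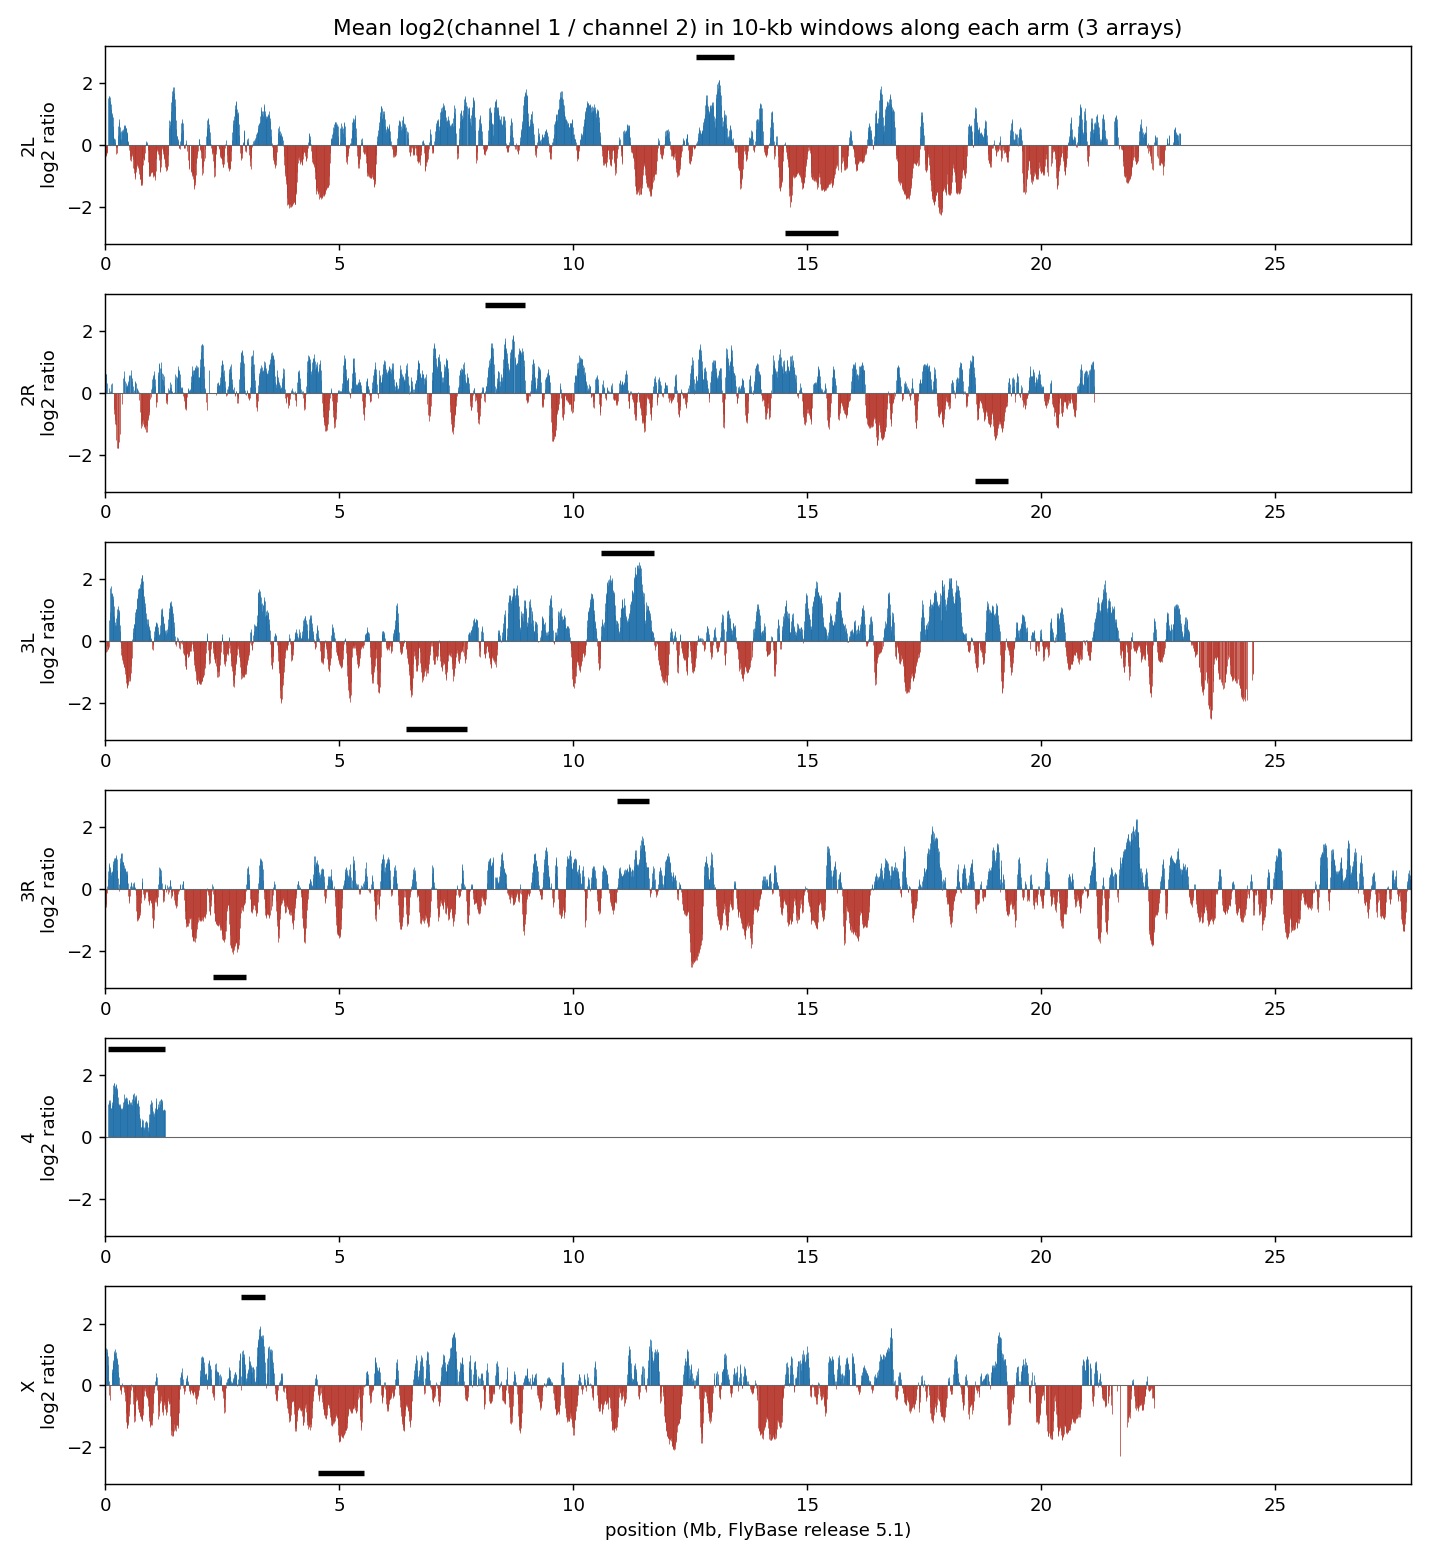
Mean log2 ratio of channel 1 over channel 2 (vertical axis, 3 arrays) in 10-kb windows against position in Mb on 2L, 2R, 3L, 3R, 4 and X, with blue above 0, red below 0 and black bars marking the longest domain in each direction. Window means run from -2.52 on 3R to 2.56 on 3L, and all 122 windows of chromosome 4 lie above 0.

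The highest and lowest windows of each arm, chosen after their values were seen, marked the ends of this range. The highest was on 3L from 11410001 to 11420000, at 2.56 ± 0.10 (SD, n = 3), a 5.92-fold excess in channel 1. On 3R the window from 22030001 to 22040000 reached 2.28 ± 0.03, and on 2L the window from 13110001 to 13120000 reached 2.11 ± 0.07. The lowest was on 3R from 12530001 to 12540000, at -2.52 ± 0.10, a 5.72-fold excess in channel 2. The lowest on 3L, from 23630001 to 23640000 near the centromere end, was -2.51 ± 0.13 but rested on 6 probes. That window moved to -1.87 with normexp on the mean and background signals and to -1.68 with the authors' deposited table. On 2L the lowest lay from 17860001 to 17870000, at -2.26 ± 0.01. The lowest on X, from 21680001 to 21690000, was -2.27 ± 0.04 and rested on 4 probes. The adjusted p of each window named here (limma) lay between 3.4e-16 and 1.0e-15. The empirical Bayes step shares variance across windows, so such small values do not rest on the 3 arrays of each window alone.

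Called windows formed domains of widely differing length. There were 350 domains higher in channel 1, with a median length of 100 kb and a total of 57.4 Mb, and 348 higher in channel 2, with a median of 90 kb and a total of 56.9 Mb. Domains of 200 kb or longer numbered 99 and 94, and those of 20 kb or shorter 43 and 47. The longest of all was a 1320-kb domain higher in channel 2 on 3L, from 6.42 to 7.74 Mb, with a mean of -0.70 ± 0.03 (SD, n = 3). The longest higher in channel 1 was chromosome 4 itself, 1220 kb from 0.06 to 1.28 Mb, at 1.02 ± 0.05. On 3L a 1140-kb domain from 10.59 to 11.73 Mb stood at 1.26 ± 0.04, a 2.40-fold excess in channel 1. On 2L the longest domains were 800 kb from 12.63 to 13.43 Mb at 0.91 ± 0.02 and 1120 kb from 14.54 to 15.66 Mb at -1.07 ± 0.03. On 2R they were 860 kb from 8.12 to 8.98 Mb at 1.00 ± 0.02 and 690 kb from 18.6 to 19.29 Mb at -0.81 ± 0.04. On 3R they were 680 kb from 10.94 to 11.62 Mb at 0.81 ± 0.02 and 710 kb from 2.3 to 3.01 Mb at -1.22 ± 0.06. On X they were 510 kb from 2.91 to 3.42 Mb at 0.90 ± 0.04 and 1000 kb from 4.54 to 5.54 Mb at -0.95 ± 0.03. Since domains were built from windows called on the same 3 arrays, their means lie away from 0 by construction. Their sizes also depended on the processing. With normexp and with the authors' deposited table, the 1140-kb domain on 3L was 1.11 and 1.01. The 710-kb domain on 3R was -1.02 and -0.96, while the 860-kb domain on 2R stayed at 1.00 with normexp and was 0.81 with the authors' table. What genes lie in these domains was not analysed here.

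**Figure D2:**
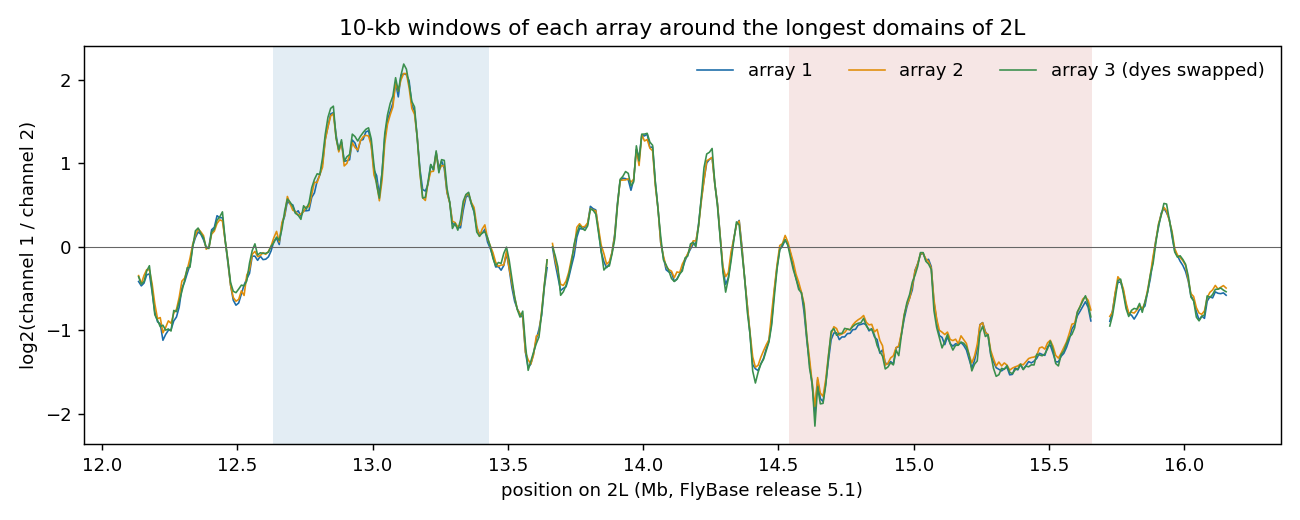
Log2 ratio of channel 1 over channel 2 in 10-kb windows (vertical axis) against position on 2L in Mb (horizontal axis), 1 line per array, with the longest domain higher in channel 1 shaded blue and the longest higher in channel 2 shaded red. The 3 arrays trace the same peaks and valleys, with domain means of 0.91 and -1.07.

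The second comparison set the chromosome arms side by side. Chromosome 4, the small dot chromosome with much heterochromatin among its genes, averaged 1.02 ± 0.05 (SD, n = 3), a 2.02-fold excess in channel 1, and all 122 of its windows were called higher in channel 1. The other arms lay near 0. The mean was 0.16 ± 0.00 on 2R and 0.07 ± 0.01 on 3L, against -0.08 ± 0.01 on 2L, -0.10 ± 0.01 on 3R and -0.17 ± 0.01 on X. On 2R, 58.7% of windows were called higher in channel 1 and 35.8% higher in channel 2, whereas X had 41.4% and 53.0%. X lay below the mean of arms 2 and 3 by 0.17 ± 0.01 on the log2 scale, in the same direction on all 3 arrays, and these arm differences exceeded the spread between arrays. An exact sign-flip test of 3 arrays gave p = 0.25, the smallest it allows. The small offsets depended on the processing: centred on the array mean in place of the median, 2L moved to -0.043, 3R to -0.066 and 3L to 0.11, and with normexp on the mean and background signals 3R moved to -0.043 and 3L to 0.10.

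The assembled heterochromatin scaffolds lay on the opposite side from chromosome 4. Pericentric heterochromatin is repeat-rich and known to replicate late in S phase. Means over windows were -1.77 ± 0.08 (SD, n = 3) on 3RHet, -1.77 ± 0.08 on XHet, -1.62 ± 0.04 on 2LHet, -1.36 ± 0.07 on 2RHet and -1.03 ± 0.03 on 3LHet. Averaged over probes, XHet was -1.62, and it moved to -1.37 with normexp and -1.41 with the authors' deposited table. By the same measure 3LHet was -1.04, and it moved to -0.83 and -0.91. Of the 398 scaffold windows, 372 were called higher in channel 2 and 23 higher in channel 1. All 10 windows of 2LHet, all 14 of XHet and all 111 of 3RHet were called higher in channel 2. The 23 exceptions were on 2RHet (10 windows) and 3LHet (13 windows). The windows with a mean above 0 lay between 2840001 and 3270000 on 2RHet, with a highest value of 1.34, and between 2190001 and 2550000 on 3LHet, with a highest value of 0.72.

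**Figure D3:**
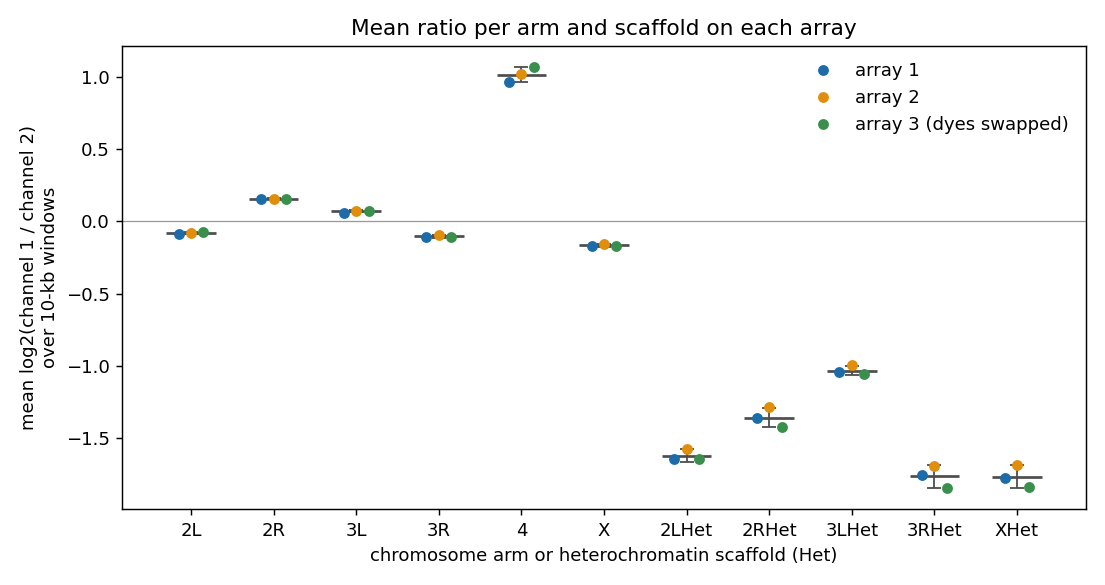
Mean log2 ratio of channel 1 over channel 2 over 10-kb windows (vertical axis) for each arm and heterochromatin scaffold (horizontal axis), with 1 point per array, a bar at the mean and an error bar of 1 SD over 3 arrays. Chromosome 4 stands at 1.02, the other arms between -0.17 and 0.16, and the scaffolds between -1.77 and -1.03.

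The third comparison asked whether the centromere end of each of the 5 major arms differed from the rest of that arm. The heterochromatin scaffolds were left out of it, so the value for 2L does not cover 2LHet, at -1.62 ± 0.04. Over 5 arms, windows in the 2 Mb nearest the centromere averaged -0.23 against -0.01 for the rest, a difference of -0.22 ± 0.01 (SD, n = 3; exact sign-flip p = 0.25, the smallest possible). The arms did not share this difference. It was -0.69 ± 0.03 on 3L and -0.32 ± 0.01 on X, -0.11 ± 0.02 on 2R and -0.06 ± 0.01 on 3R, while 2L went the other way at 0.09 ± 0.02. These differences depended on the processing. With normexp on the mean and background signals, the mean over arms moved to -0.11, with 3L at -0.56, X at -0.24, 2R at -0.00098, 3R at -0.029 and 2L at 0.26, while 2L was 0.044 with loess and 0.037 with the authors' deposited table. They also depended on how much sequence was taken. Over the nearest 1 Mb alone the mean difference was -0.37, with 3L at -1.46, 2R at -0.44 and 3R turned to 0.28.

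The scale of the profile was read from neighbouring windows. Window means 10 kb apart correlated at 0.978, those 100 kb apart at 0.544, those 200 kb apart at 0.348 and those 500 kb apart at 0.08, across windows. A profile smoothed over 50 kb had 340 maxima with a prominence of at least 0.5 on the log2 scale, a median of 310 kb apart. Of these, 320 were found on all 3 arrays within 20 kb, which is not an independent check, since the profile was the mean of the same arrays. A maximum is relative to its neighbours: 49 of the 340 had a smoothed ratio below 0. Adjacent maxima and minima lay a median of 130 kb apart and differed by a median of 1.25. The steepest passage was on 3R between 21120001 and 21240000, where the smoothed ratio changed by 2.92 over 110 kb.

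Besides the ratio, the total signal of both channels varied along the arms. On 2L, probes from 2 to 11 Mb had a median log2 total signal, corrected for probe GC and length, of -0.36 ± 0.01 (SD, n = 3), and those from 15 to 22 Mb of 0.39 ± 0.01. Against the median of all arm probes, the first of these blocks was lower in both channels, at -0.31 ± 0.02 in channel 1 and -0.49 ± 0.01 in channel 2, and the second was higher in both, at 0.19 ± 0.01 and 0.56 ± 0.01. On X, probes from 1 to 4 Mb stood at -0.35 ± 0.01 and those from 4 to 11 Mb at 0.17 ± 0.00. The first of these was lower in both channels, at -0.37 ± 0.02 in channel 1 and -0.48 ± 0.01 in channel 2, whereas the second was higher in channel 2 alone, at 0.26 ± 0.01 against -0.036 ± 0.007 in channel 1. The last part of 2R, from 20 to 21 Mb, stood at -0.52 ± 0.03, with -0.69 ± 0.06 in channel 1 and -0.55 ± 0.04 in channel 2. The channels did not move together in every block: from 1 to 5 Mb on 3R they lay on opposite sides of 0, with channel 1 at -0.46 ± 0.03 and channel 2 at 0.068 ± 0.005. These blocks were chosen after their values were seen. Over all 242 windows of 500 kb, the signals of channels 1 and 2 correlated at -0.075 across windows.

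**Figure D4:**
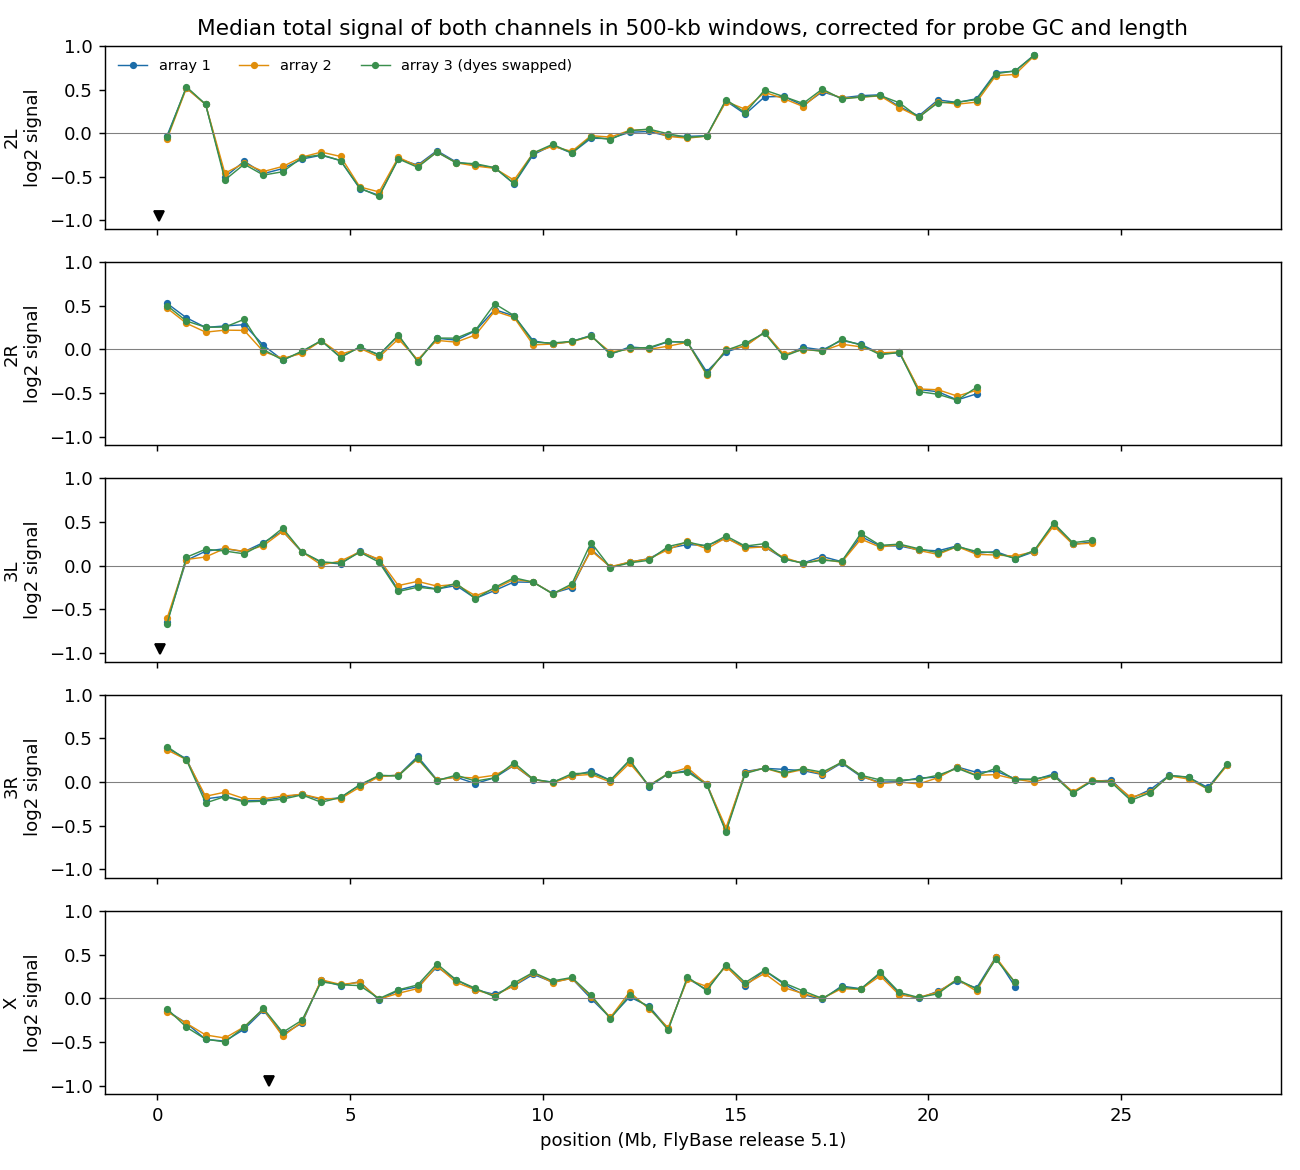
Median log2 total signal of both channels in 500-kb windows (vertical axis), corrected for probe GC and length, against position in Mb on 2L, 2R, 3L, 3R and X, 1 line per array, with triangles at stretches of probes near the level of negative controls. On 2L the block from 2 to 11 Mb lies at -0.36 and the block from 15 to 22 Mb at 0.39.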

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

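The items here come from probes outside the comparisons, the Y chromosome scaffold and the unplaced scaffold. A larger share of them than of negative control spots was well above background. Of 158 probes on the Y scaffold, 81 (51.3%, 95% Wilson interval 43.5 to 58.9%) were well above background in both channels of all 3 arrays, although the cell line is labelled female. The corresponding count was 60 of 1275 (4.71%, interval 3.67 to 6.01%) for negative control spots and 236028 of 236742 for arm probes. The Y probes were nevertheless dim, with a median log2 total signal of 5.36 ± 0.64 (SD, n = 3) against 10.24 ± 0.03 for arm probes and 4.32 ± 0.47 for negative controls, and 8 of them came within 1 of the arm median or above it. Their median lay under 6.29, the 99th percentile of negative control spots used to mark dim probes, so most of these probes were near the level of negative controls. On the unplaced scaffold, 1060 of 1243 probes (85.3%, interval 83.2 to 87.1%) were well above background in both channels of all 3 arrays, with a median log2 total signal of 9.59 ± 0.04 and a mean log2 ratio of -1.24 ± 0.05. The intervals treat probes as independent and cover counting error only.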

How the results depend on the processing

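Under the alternatives run, 149 of 180 values of the main comparisons stayed within the spread between arrays or within 1.5 times the count reported. None of the 180 changed sign, but many are counts, which cannot. Some agreement is also fixed in advance: centring on the mean cannot move the proximal difference or the correlations between arrays. Leaving out 1 of the 3 arrays likewise cannot move a mean by more than 1 SD over arrays, so those settings are no test of the means. Of 368 values for single domains, windows, scaffolds and arm ends, 80 moved by more than 1 SD. A further 1 reversed: the proximal difference on 3R, 0.28 over the nearest 1 Mb. Of the 80, 30 moved with the authors' deposited table and 29 with normexp, which is nearly all of the values computed with either setting. The total of 368 also counts settings that changed few probes, such as leaving out saturated probes. In 5-kb windows 10951 were called higher in channel 1 and 10792 higher in channel 2, and in 50-kb windows 1157 and 1146, which follows from the number of windows tested (22986 and 2397). With array 3 not turned, 0 and 0 windows were called by limma, and 0 passed an unadjusted p of 0.05. This follows from how closely the arrays agreed: with 1 of 3 reversed, the spread between arrays exceeds the mean. With normexp on the mean and background signals, 67871 probes were called higher in channel 1 and 70900 higher in channel 2. The mean correlation of arrays fell there to 0.797 across probes and 0.957 across windows. Its arm means were -0.055 on 2L, 0.17 on 2R, 0.10 on 3L, -0.043 on 3R and -0.12 on X, and the proximal difference was -0.11. With loess, 2R was 0.15, 3L 0.061 and the proximal difference -0.24. With the authors' deposited table, 2R was 0.12, 3L 0.046, 3R -0.086, chromosome 4 0.82, X -0.14, the proximal difference -0.20 and the correlation across probes 0.982. Centred on the mean, 2L was -0.043, 2R 0.19, 3L 0.11, 3R -0.066 and X -0.13, a shift set by the centring itself. For the other moves the cause was not tested. The nearest 1 Mb gave a proximal difference of -0.37. Chosen after seeing the data, leaving out dim windows gave 5646 and 5571 called windows, and counting only windows beyond 0.5 gave 291 and 284 domains. A dye term gave 5706 and 5643 called windows, and in that fit 592 windows had a dye effect at an adjusted p under 0.05 (limma). Only array 3 had the reversed orientation, so a dye effect cannot be told apart from a difference of that array. The ratio within each array already pairs both populations, and with 1 group no further block was fitted. Results by gene, gene list, gene density and feature class were not run. Signal over background limits few arm probes, 99.7% being well above background in all channels.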

Other observations

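The tests of dye bias and of sequence labelled in neither window, and the choice of stretches and blocks along the arms, were made after the values they concern had been seen. The steps in total signal that both channels shared, such as those on 2L, may reflect segments of unequal copy number in this cell line. This is a hypothesis with no direct test here, since no array of unlabelled genomic DNA was analysed. Over all windows of 500 kb the signals of the 2 channels correlated at -0.075, which does not settle it, since a timing difference moves the channels apart. Probe composition accounts for little of it, as correction for GC and length lowered the SD over 242 windows of 500 kb by 4.41 ± 0.42% (SD, n = 3). Sequence that escaped both labelling periods stays open. The 100-kb windows with ratios between -0.25 and 0.25 differed from the dimmer of the outer classes (ratios above 1 or below -1) by 0.0019 ± 0.047 (bootstrap SE). This comparison cannot decide it, since a mean of log2 signals also falls when the channels move apart at equal summed signal. The lowest correlation between 2 arrays over the 500-kb windows was 0.994.

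Probes at the tips of 2L and 3L were near the level of negative controls. On 2L from 5731 to 58561, 65 of 93 probes fell under the 99th percentile of negative control spots, and on 3L from 20861 to 95631, 86 of 154 did. Total signal there differed from the arm median by -4.71 ± 0.70 and -4.04 ± 0.47 on the log2 scale (SD, n = 3). With most probes at the level of negative controls, these values are limited by background and are not exact sizes of a loss. Probe GC and length predicted a change of 0.094, not a loss. Replication outside both labelling periods would predict a gradual loss, but the next 50 kb lay at 0.41 ± 0.04 from the arm median on 2L and at -0.14 ± 0.07 on 3L (0.17 over both), each within the 0.5 set as the bound. Sequence missing or diverged in this cell line is a candidate explanation and was not tested. A stretch of the same kind, 33 probes from 2893981 to 2909571 on X, lay away from the chromosome end. Its change of -4.32 ± 0.53 was limited by background in the same way, with 22 of the 33 probes under that percentile.

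The excess of channel 1 on chromosome 4 (1.02 ± 0.05 over probes) was weighed against technical sources. After correction for probe GC the mean was 1.02 ± 0.04. The dye part of the ratio, 0.5 times the difference between orientations, was -0.038. Arm probes matched in brightness averaged -0.011 ± 0.010. None of these accounts for a value near 1. A timing difference of the whole chromosome stays a hypothesis that had no test of its own here. The excess was found, and the technical sources were tested, on the same data.

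For the heterochromatin scaffolds, the mean over 3326 probes was -1.37 ± 0.06, that of 1645 probes of ordinary brightness -1.44 ± 0.07, that after GC correction -1.37 ± 0.06, and that of brightness-matched arm probes -0.00 ± 0.01. As for the count of called windows, the labelled dyes gave 11228 and the highest of the other sign patterns 0. Of 4 sign patterns, 1 gave as many windows, and 4 patterns are too few for a share under 0.05. The 0 itself was set by the close agreement of the arrays, since reversing 1 of them makes the spread exceed the mean.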
